A study of Mus musculus with 6 samples.

How the data were processed

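RNA sequencing was analysed for 6 samples of donor CD8+ T cells sorted from mouse spleen on day 7 of infection, 3 with the control label and 3 with the knockout label. Per the labels' protocols, RNA was isolated with a column kit and sent to a commercial provider for library construction and sequencing. The submitters' processing notes name the mm10 genome build. The aligner, the counting program, the gene annotation and the use of strand are not given in the sources used here.

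The values are a signal on a linear scale that the deposited table calls normalized counts: each sample's gene counts appear, from the values themselves, to have been divided by 1 factor per sample by the authors. Every value was a whole multiple of the step of its column (100% of values whole within a tolerance of 0.01, against 1.43% to 1.76% before division by the step), so the reads behind each value could be recovered. For control-labelled library 2 and knockout-labelled library 3 the step lies near 1, and a further check of whole reads was not applied. Their reads rest on the same division, with 1.67% and 1.59% of values whole before it and 100% after. Recovered reads ranged from 14746864 to 22931296 per library, which is the depth over the listed genes and not over all reads sequenced. The table lists 13675 genes, and the lowest mean was 9.69 normalized counts. Genes were identified by Ensembl gene IDs, of which 13648 were matched to a symbol and coordinates in GENCODE M21 on GRCm38, the assembly also called mm10, and 27 were not. No column belonged to another sample. Libraries were compared in pairs by chi-square over the recovered reads, and none of the pairs agreed within sampling noise (chi-square per degree of freedom 5.32 or more), so each was counted as a separate sample.

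The 1 comparison the design gives, knockout-labelled minus control-labelled libraries, was tested with limma 3.58.1 in R 4.3.3 (linear fit, empirical Bayes with a variance trend, two-sided) on log2 of the normalized count plus a pseudocount of 1. Genes with a mean of at least 10 normalized counts over the 6 libraries were tested (13654), and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on this scale, which understates the change of low genes. Each p in the text is from this limma fit unless another test is named. For Csnk2a1 an exact two-sided permutation test of the 6 values was run as well.

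Before the data were examined, 37 gene lists were fixed from general knowledge of CD8+ T cells and CK2, 27 of cell programmes and 10 of markers of other cell types that a spleen sort could hold. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 37 lists, which asks whether a list moved relative to other genes. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way and compares them with no other genes, were run beside it. With the preset correlation 17 of 37 lists were called, 12 higher and 5 lower, with an estimated correlation 0 (smallest adjusted p 0.113), and by fry 7. Fry called each of the 5 that camera called lower and none of the 12 it called higher. The other lists fry called were those of CK2 subunit and trafficking genes. Members of each list were also adjusted over the list alone.

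The rule for named genes was fixed at the same time: the CK2 subunit genes, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 normalized counts and groups that did not overlap, up to 4 members of each described list with the smallest p and any member that passed, and 17 genes of CD8+ T cell differentiation. Some genes that the rule takes in are not reported here. Hspa1b, Xist and Cd79a were singled out after their values were seen, as were the alternatives without knockout-labelled libraries 2 and 3 and with the B cell transcript level as a covariate (the mean of 11 markers, with Cd22 and Ighm set apart after their values were seen, and also the mean of all 13).

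Alternatives planned beforehand were a pseudocount of 0.5 or 5, no filter or a filter at a mean of 50, TMM factors, quantile normalization, no variance trend, array weights, a replicate block, a minimum of 2-fold, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. edgeR called 645 genes and DESeq2 1023. The limma step was tested on simulated counts with the means and depths of this comparison (5 runs of 13675 genes). It called 48.1% of genes changed 1.5-fold, 75% of those changed 2-fold and 94.2% of those changed 4-fold, and 8.53% of its calls were unchanged genes. A simulated list changed 1.3-fold was called in 5 of 5 runs and 0 of 180 other lists were, with genes simulated as independent of one another.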

Results

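CK2 is a serine/threonine protein kinase built from catalytic subunits, CK2α (gene Csnk2a1) and CK2α′ (gene Csnk2a2), and a regulatory subunit, CK2β (gene Csnk2b). The study asked how loss of CK2α in CD8+ T cells alters their response to infection. Its cells were OT-I cells, CD8+ T cells of a mouse line whose transgenic receptor recognises a peptide of ovalbumin. They either carried the CK2α gene with loxP sites and no Cre, the control label, or also carried Cre recombinase under the distal Lck promoter, which is active in maturing T cells, the knockout label. The 2 kinds of cells were given to separate host mice, the hosts were infected with Listeria monocytogenes engineered to express ovalbumin, and the donor cells were sorted from the spleen on day 7, told from host cells by a CD45 allele. RNA sequencing was done on 3 samples of each label. The table lists normalized counts for 13675 genes, and the reads recovered from it numbered 18226879, 19480791 and 22931296 in control-labelled libraries 1, 2 and 3, and 20140111, 14746864 and 18279680 in knockout-labelled libraries 1, 2 and 3. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

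The targeted gene was higher, not lower, in the knockout-labelled libraries. Csnk2a1 (ENSMUSG00000074698, GRCm38 chromosome 2, 152226839 to 152281852) measured 1665, 1847 and 1645 normalized counts in the control-labelled libraries and 2828, 2875 and 2786 in the knockout-labelled libraries. The means were 1719 ± 112 (SD, n = 3) and 2830 ± 44.3 (SD, n = 3), a log2 fold change of 0.72 (SE 0.07) or 1.65-fold (limma, adjusted p = 0.000865). The exact two-sided permutation p of the 6 values was 0.1, the smallest that 3 against 3 can give. This goes against the label, so all directions here are given as knockout-labelled against control-labelled libraries. The labels do not give the deleted exons, and a count over the whole gene includes reads from any exons that remain, so the value does not check the deletion. The other catalytic subunit gene, Csnk2a2, measured 1614 ± 18.9 and 1609 ± 44.6 normalized counts (SD, n = 3 each; log2 fold change -0.0045, 95% interval -0.15 to 0.14), with a sign that turned under another scaling of the libraries (0.01 with TMM factors, 0.03 after quantile normalization). Csnk2b measured 2287 ± 217 and 2317 ± 51 (log2 fold change 0.02, 95% interval -0.15 to 0.20, adjusted p = 0.908). Of the 3 CK2 subunit genes, 1 rose and none fell, and 1 rose when adjusted over the list alone. The list as a whole was not called (camera, adjusted p = 0.12), but it was called higher after quantile normalization (0.0359), with edgeR (0.00604) and with DESeq2 (0.00692). Fry, which tests whether members move on balance one way, called it higher too (adjusted p = 0.0247). Camera with an estimated correlation did not call it (adjusted p = 0.571).

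**Figure D1:**
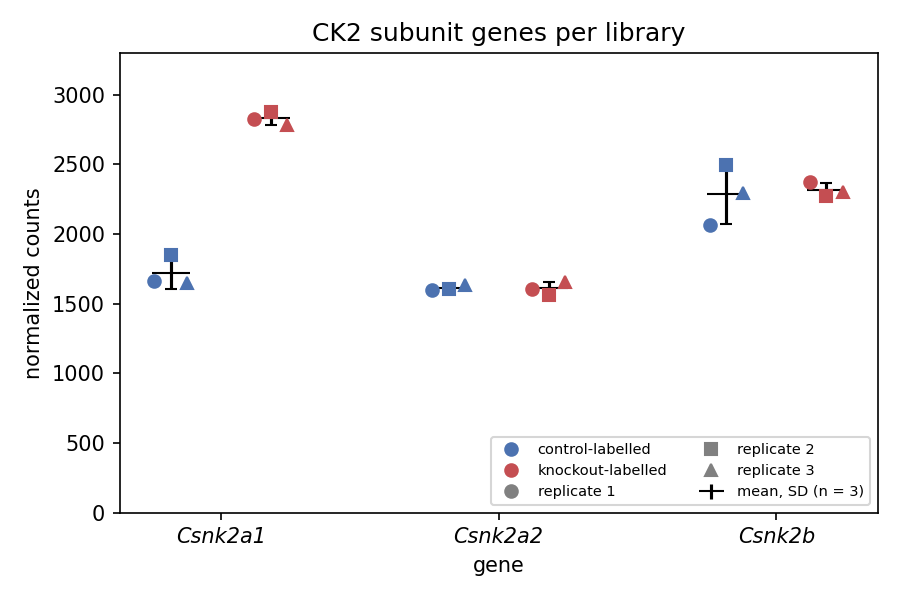
Normalized counts (vertical axis, linear, from 0) of the 3 CK2 subunit genes (horizontal axis) in each library, with the group mean and SD (n = 3) as black bars. Csnk2a1 lies between 1645 and 1847 in the control-labelled libraries and between 2786 and 2875 in the knockout-labelled libraries, while the groups overlap for Csnk2a2 and Csnk2b.

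In all, 278 genes were higher and 430 lower in the knockout-labelled libraries (708 of 13654 tested, limma, adjusted p below 0.05). Of these, 101 rose and 39 fell by at least 2-fold, and the median size of a called change was 0.58 on the log2 scale. Among the 10 largest rises with a mean of at least 50 normalized counts were those of Lmo1, Dlg5, Echdc2, Espn, Cdr2l, Asns, Itgad, Gng3 and Syk. Espn, which encodes an actin-bundling protein, rose from 69.6 ± 3.77 to 295 ± 33.4 normalized counts (SD, n = 3; 4.18-fold, log2 fold change 2.06, SE 0.14, adjusted p = 0.000154). Itgad, an integrin alpha chain, rose from 138 ± 2.1 to 521 ± 111 (3.72-fold, adjusted p = 0.000325), and Asns, asparagine synthetase, from 28.5 ± 4.56 to 118 ± 16.1 (4.04-fold, adjusted p = 0.00108). Lmo1 (log2 fold change 2.97, SE 0.50), Dlg5 (2.34, SE 0.39), Echdc2 (2.11, SE 0.22), Cdr2l (2.03, SE 0.16) and Gng3 (1.87, SE 0.22) rose in a like manner. Syk, a kinase of B cell receptor signalling, was not level across the knockout-labelled libraries. It measured 241, 609 and 571 normalized counts in knockout-labelled libraries 1, 2 and 3 against 133 to 137 in the controls (log2 fold change 1.69, SE 0.29).

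The 10 largest falls were those of 5830444B04Rik, Cd40lg, Arhgap23, Itga2, Tmprss13, Gm4208, Cfap74, Serpinb1a, Metrnl and Ltb4r1. Cd40lg, the ligand of the costimulatory receptor CD40, fell from 165 ± 11.1 to 46.3 ± 7.86 normalized counts (SD, n = 3; 3.54-fold lower, log2 fold change -1.82, SE 0.18, adjusted p = 0.000865). Itga2, an integrin chain that pairs with beta1 to bind collagen, fell from 275 ± 84.5 to 85.8 ± 10.9 (3.11-fold lower, adjusted p = 0.00261), and Tmprss13, a transmembrane serine protease, from 391 ± 25.4 to 128 ± 18.3 (3.06-fold lower, adjusted p = 0.000359). Serpinb1a, an inhibitor of neutrophil-type serine proteases, was 2.79-fold lower and Ltb4r1, a leukotriene B4 receptor, 2.52-fold lower. Gm4208, a long non-coding RNA gene, was 2.98-fold lower, Arhgap23 3.22-fold and Metrnl 2.78-fold. 5830444B04Rik (GRCm38 chromosome 4, 155398763 to 155421704, minus strand, 4.08-fold lower) and Cfap74 (155409190 to 155466823, plus strand, 2.79-fold lower) overlap on opposite strands, and as it is not given whether reads were counted by strand, the values of the pair are uncertain. With 1 library left out at a time, Espn, Itgad, Asns, Echdc2, Cdr2l, Gng3, Cd40lg, Itga2, Tmprss13, Gm4208, Serpinb1a, 5830444B04Rik and Cfap74 passed in 6 of 6 runs, Dlg5 in 5 (adjusted p = 0.0642 without knockout-labelled library 3), Lmo1 and Syk in 4 (up to 0.0598 and 0.0664, lost without knockout-labelled library 2 or 3), Ltb4r1 in 2 (up to 0.102), and Arhgap23 and Metrnl in 1 (up to 0.124 and 0.108). The number of calls was 141 without a variance trend and 2676 with array weights. It rested strongly on single libraries. It was 2028 without control-labelled library 2 and 200 without knockout-labelled library 3. It was 370 and 228 without control-labelled library 1 or 3 and 440 and 320 without knockout-labelled library 1 or 2. Without knockout-labelled libraries 2 and 3 together it was 0 by limma and 0 by edgeR, with 1861 and 1862 genes at an unadjusted p below 0.05, so that no gene named here passed in that run. That run kept 1 knockout-labelled library, so the loss of calls cannot tell lower power from changes confined to libraries 2 and 3. The 705 called genes tested in it all kept their sign, as genes with groups that do not overlap must. With the B cell transcript level as a covariate, chosen after seeing the data, 135 genes were called (49 higher and 86 lower). With all 13 markers in the covariate 86 were called. The 708 genes of the main fit all kept their sign with either covariate. All 708 called genes had groups that did not overlap, as did 25.7% of all tested genes against 10% by chance.

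Of 23 genes of terminal effector differentiation 8 fell and 2 rose in the knockout-labelled libraries, and 2 transcription factor genes tied to memory potential, Tcf7 and Id3, rose. Tcf7, which encodes TCF-1, a factor of naive and memory T cells, rose from 8742 ± 1184 to 13427 ± 829 normalized counts (SD, n = 3; 1.54-fold, log2 fold change 0.63, SE 0.10, adjusted p = 0.0071). Id3, an inhibitor of E-protein factors linked to memory precursors, rose from 260 ± 30.2 to 461 ± 51 (1.77-fold, adjusted p = 0.00544). Its counterpart in effector cells, Id2, fell from 7803 ± 380 to 5791 ± 725 (1.35-fold lower, adjusted p = 0.0247), and Prdm1, which encodes the effector factor Blimp-1, fell from 1107 ± 156 to 694 ± 23.8 (1.58-fold lower, adjusted p = 0.00715). Cx3cr1, a chemokine receptor of terminal effectors, was 1.76-fold lower (adjusted p = 0.0276) and Zeb2, a repressor that promotes terminal differentiation, 1.72-fold lower (adjusted p = 0.0498). For both of these, control-labelled library 2 lay near the knockout-labelled libraries. Zeb2 measured 5845, 3168 and 5653 normalized counts in control-labelled libraries 1, 2 and 3 and 2469, 3002 and 2797 in the knockout-labelled ones, and Cx3cr1 14040, 8790 and 14302 against 5876, 8056 and 6857.

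Of the 23 measured genes on the terminal effector list, 8 fell, 2 rose and 13 did not pass (13 fell and 2 rose when adjusted over the list alone). Besides those above, the falls were those of Klrk1, the activating receptor NKG2D (1.72-fold lower, adjusted p = 0.00113), Itgam and Itgax, the integrin chains CD11b and CD11c (1.85-fold and 1.40-fold lower), and Anxa1 (1.47-fold lower). Among the rises was that of S100a4, a calcium-binding protein (1.37-fold). Without control-labelled library 2, 13 members of the list were called lower and 3 higher. With a median log2 fold change of -0.34, the list was called lower (camera, adjusted p = 2.05e-05), a call lost with an estimated correlation (adjusted p = 0.177). Fry called the list lower too (adjusted p = 0.0156). The best known surface marker of terminal effectors, Klrg1, measured 5393 ± 1007 and 4203 ± 333 normalized counts and did not pass (log2 fold change -0.34, SE 0.13, adjusted p = 0.151), nor did Tbx21, which encodes T-bet (-0.26, SE 0.10, adjusted p = 0.153). With 1 library left out at a time, Tcf7, Id3, Klrk1, Itgam and Itgax passed in 6 of 6 runs and Prdm1 in 5 (adjusted p = 0.0502 without knockout-labelled library 3). Anxa1 passed in 3, Id2 in 2, and S100a4, Cx3cr1 and Zeb2 in 1, that without control-labelled library 2, with adjusted p reaching 0.0959, 0.119, 0.159, 0.117 and 0.18 in the others. The median of the list in knockout-labelled library 1, where B cell transcripts were at the control level, was -0.29 against the control mean, and -0.31 and -0.44 in knockout-labelled libraries 2 and 3, where they were raised.

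Of the 25 measured genes on the memory precursor and naive-like list, 4 rose, 2 fell and 19 did not pass (8 rose and 4 fell when adjusted over the list alone). Without control-labelled library 2, 10 were called higher and 3 lower. Besides Tcf7 and Id3, Ltb, which encodes lymphotoxin beta, rose 1.33-fold and Dapl1, a gene of naive and memory T cells, 1.88-fold. Klf2, a factor that controls T cell recirculation, fell 1.43-fold and its target S1pr1, the receptor that lets T cells leave lymphoid tissue, 1.23-fold. As a list they were called higher (camera, adjusted p = 0.0428; adjusted p = 0.571 with an estimated correlation), and its call was lost in 4 of the runs that left out 1 library, those without control-labelled library 1 (adjusted p = 0.0982) or 3 (0.182) or knockout-labelled library 1 (0.0845) or 3 (0.0767), and without knockout-labelled libraries 2 and 3 together (0.068). The median of the list in control-labelled library 2 was 0.19 above the control mean on the log2 scale, within the 0.20, 0.08 and 0.20 of the knockout-labelled libraries, and it was -0.04 and -0.09 in control-labelled libraries 1 and 3. Among single genes, Ltb and Klf2 passed in 2 of 6 such runs, and Dapl1 and S1pr1 in 1, that without control-labelled library 2 (adjusted p reaching 0.126, 0.0822, 0.133 and 0.16 in the others). Il7r, the interleukin-7 receptor of memory precursors, did not pass (log2 fold change 0.15, 95% interval -0.10 to 0.39, adjusted p = 0.483), nor did Eomes (0.21, SE 0.14, adjusted p = 0.417), Bcl2 (-0.48, SE 0.14, adjusted p = 0.0757) or Pdcd1 (0.50, SE 0.33, adjusted p = 0.418).

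**Figure D2:**
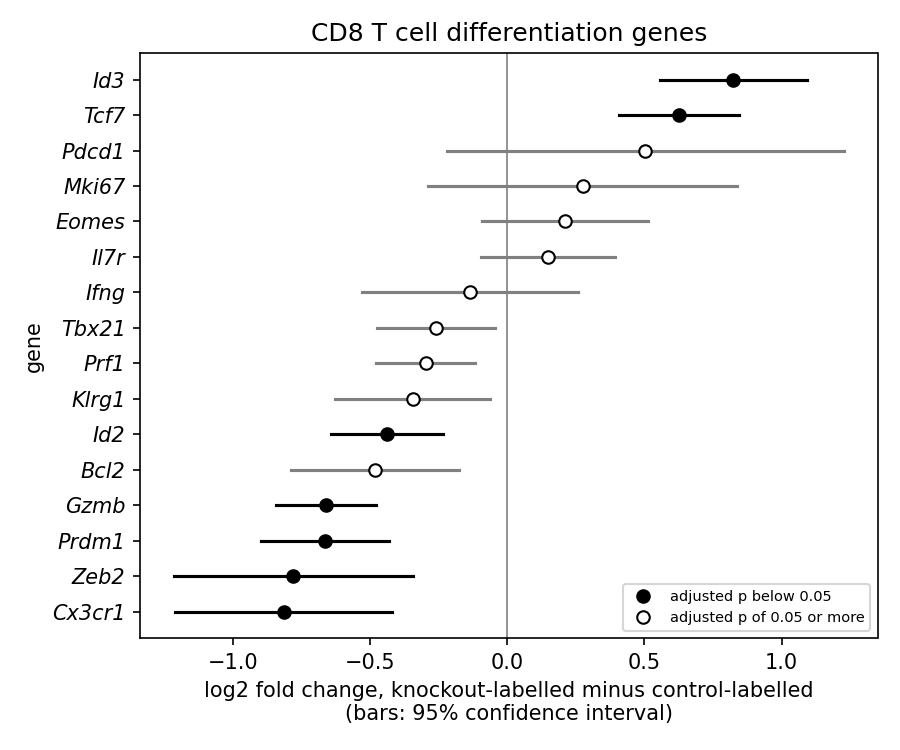
Log2 fold change of knockout-labelled minus control-labelled libraries (horizontal axis) with its 95% confidence interval for differentiation genes fixed in advance (vertical axis; n = 3 per group; filled points have an adjusted p below 0.05). Id3 (0.82) and Tcf7 (0.63) lie to the right of 0, and Id2, Gzmb, Prdm1, Zeb2 and Cx3cr1 lie to the left, from -0.44 to -0.81.

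Cytotoxic effector genes moved in both directions. Gzmb, which encodes granzyme B, the main apoptosis-inducing granule protease of effector cells, fell from 13274 ± 1182 to 8394 ± 402 normalized counts (SD, n = 3; 1.58-fold lower, log2 fold change -0.66, SE 0.08, adjusted p = 0.00241). The other granzymes that passed rose. Gzmk went from 2196 ± 359 to 4642 ± 356.5 (2.13-fold, adjusted p = 0.00101), Gzmm rose 1.68-fold (adjusted p = 0.00868) and Gzma 1.43-fold (adjusted p = 0.0422). Tnf, an inflammatory cytokine, rose from 162 ± 34.8 to 367 ± 47.2 (2.28-fold, adjusted p = 0.00489), whereas Cst7, the protease inhibitor cystatin F, fell 1.33-fold and Tnfsf10, the death ligand TRAIL, 1.27-fold. Of 20 measured genes on the list, 4 rose and 3 fell (4 and 6 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.246). Prf1, which encodes perforin, measured 5763 ± 375 and 4695 ± 391 normalized counts and did not pass (log2 fold change -0.30, SE 0.08, adjusted p = 0.0659). Ifng did not pass either (-0.14, 95% interval -0.53 to 0.26, adjusted p = 0.717), with a sign that turned when control-labelled library 3 was left out (0.05). Gzmb, Gzmk, Gzmm and Tnf passed in 6 of 6 runs that left out 1 library, Cst7 in 3 (adjusted p up to 0.0903 without control-labelled library 3 or knockout-labelled library 2 or 3), and Gzma and Tnfsf10 in 1, that without control-labelled library 2 (up to 0.157 and 0.124 in the others).

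Of 22 genes of the T cell receptor complex and proximal signalling 3 fell, and of 32 genes of cytokine signalling 6 fell, with none rising in either list. Cd6, a receptor that tunes T cell receptor signals, fell from 8800 ± 533 to 3918.5 ± 249.5 normalized counts (SD, n = 3; 2.25-fold lower, log2 fold change -1.17, SE 0.08, adjusted p = 0.000154), and the related Cd5 fell from 5836 ± 362 to 3237 ± 369 (1.81-fold lower, adjusted p = 0.00114). Ptpn6, the phosphatase SHP-1, was 1.39-fold lower. Of the 22 measured genes on the list of receptor complex and proximal signalling genes these 3 fell, none rose and 19 did not pass (7 fell and none rose when adjusted over the list alone). Of the 22, 20 had a negative log2 fold change, and the list was called lower (camera, adjusted p = 3.85e-06, but 0.548 with an estimated correlation). By fry it was called lower as well (adjusted p = 0.0247). Plcg1 was the closest to passing (log2 fold change -0.32, SE 0.08, adjusted p = 0.0511). Of the 32 measured genes of JAK-STAT and common gamma chain cytokine signalling, 6 fell and none rose (9 fell and 2 rose when adjusted over the list alone). Il12rb2, the signalling chain of the interleukin-12 receptor, fell from 710 ± 39.5 to 323 ± 55.5 (2.21-fold lower, adjusted p = 0.00111). Il6st, the shared gp130 chain of the interleukin-6 family, fell 1.74-fold, Il2ra, the high-affinity interleukin-2 receptor chain, 1.67-fold, Il10ra 1.49-fold, Ifngr1 1.41-fold, and the kinase Jak1 1.38-fold. Together the 32 were called lower (camera, adjusted p = 0.000344, but 0.177 with an estimated correlation), also by fry (adjusted p = 0.00219). Cd6, Cd5, Il12rb2, Il6st, Il10ra and Ifngr1 passed in 6 of 6 runs that left out 1 library, Il2ra in 5 (adjusted p = 0.0647 without control-labelled library 3), Ptpn6 in 4 (up to 0.0875 without control-labelled library 3 or knockout-labelled library 3) and Jak1 in 3 (up to 0.101 without control-labelled library 3 or knockout-labelled library 2 or 3). Against the control mean, the median of the receptor list was -0.16, -0.14 and -0.18 in knockout-labelled libraries 1, 2 and 3. That of the cytokine list was -0.13, -0.11 and -0.12.

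PI3K, AKT and FOXO signalling carries growth factor and receptor signals to metabolism and trafficking. Of 25 measured genes on the list for this pathway, 8 fell, none rose and 17 did not pass (9 fell and none rose when adjusted over the list alone). The list includes Pdk1, which in mouse is pyruvate dehydrogenase kinase 1 and not the kinase of this pathway (log2 fold change -0.10, not called). Pik3ip1, a negative regulator of PI3K, fell from 1503 ± 112 to 974 ± 17.2 normalized counts (SD, n = 3; 1.54-fold lower, adjusted p = 0.00231). Sesn1, a stress-induced inhibitor of mTORC1 and a FOXO target, fell by 0.59 on the log2 scale, Rptor, the raptor subunit of mTORC1, 1.44-fold, Foxp1, a factor of T cell quiescence, 1.34-fold, Ccng2, a FOXO target, 1.34-fold, and Foxo3 1.39-fold. Klf2 and S1pr1, given above, are on this list too. The list had a median log2 fold change of -0.20 and was called lower (camera, adjusted p = 1.52e-07, but 0.113 with an estimated correlation). Fry called it lower too (adjusted p = 0.000687). Its median was -0.28, -0.17 and -0.19 against the control mean in knockout-labelled libraries 1, 2 and 3. Pik3ip1, Sesn1, Rptor and Foxp1 passed in 6 of 6 runs that left out 1 library, Ccng2 in 4 (adjusted p up to 0.0657 without control-labelled library 3 or knockout-labelled library 3), and Foxo3 in 1, that without control-labelled library 2 (up to 0.181 in the others).

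Of 23 measured chemokine receptor, integrin and trafficking genes, 3 rose, 7 fell and 13 did not pass (5 rose and 8 fell when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.103). It was called lower with edgeR (adjusted p = 0.0356), with DESeq2 (0.0339) and by fry (0.0147), but not by camera with an estimated correlation (0.548). Itga1, a collagen-binding integrin chain, fell from 404 ± 98 to 183 ± 27.8 normalized counts (SD, n = 3; 2.17-fold lower, adjusted p = 0.00797), and its partner chain Itgb1 fell 1.34-fold. Cxcr4 fell 1.38-fold, S1pr4 1.32-fold and Selplg, the selectin ligand PSGL-1, 1.31-fold, beside Cx3cr1 and S1pr1. Among the rises, Itgae, the integrin chain CD103, went from 109 ± 39.6 to 245 ± 60.6 (2.31-fold, adjusted p = 0.0367), and Cxcr5, the receptor for the B cell follicle chemokine CXCL13, from 170 ± 9.43 to 271 ± 8.77 (1.59-fold, adjusted p = 0.00868). Itga1 passed in 6 of 6 runs that left out 1 library and Cxcr5 in 4 (adjusted p up to 0.0588 without control-labelled library 3 or knockout-labelled library 3). Itgb1, Cxcr4, S1pr4, Selplg and Itgae passed in 2, lost without control-labelled library 3 and 3 other libraries each (up to 0.118, 0.132, 0.113, 0.179 and 0.166).

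Of 30 measured interferon-stimulated genes, 5 rose, 1 fell and 24 did not pass (9 rose and 2 fell when adjusted over the list alone). Without control-labelled library 2, 14 were called higher and 1 lower. Irf7, a transcription factor of the interferon response, rose from 1541 ± 31.9 to 2072 ± 83.6 normalized counts (SD, n = 3; 1.34-fold, adjusted p = 0.00695), Rtp4 1.86-fold, Isg20 1.62-fold, Oas1a 1.60-fold and Ifih1, the RNA sensor MDA5, 1.43-fold. Ly6c2, a surface marker of activated CD8+ T cells that is also interferon-responsive, fell 1.44-fold (adjusted p = 0.00429). As a list, interferon-stimulated genes were called higher (camera, adjusted p = 7.63e-06, but 0.571 with an estimated correlation). Their median against the control mean was 0.41, 0.17 and 0.22 in knockout-labelled libraries 1, 2 and 3. In control-labelled libraries 1, 2 and 3 it was -0.11, 0.13 and -0.05. All 26 measured genes of ribosome biogenesis and MYC targets had a positive log2 fold change. Of these, 4 rose, namely Gnl3 (1.44-fold, adjusted p = 0.0117), Mrto4 (1.37-fold), Nop2 (1.26-fold) and Nolc1 (1.23-fold), all of them nucleolar factors, and 22 did not pass (8 rose when adjusted over the list alone). That list was called higher (camera, adjusted p = 1.52e-07, but 0.548 with an estimated correlation). Its median against the control mean was 0.25, 0.16 and 0.20 in knockout-labelled libraries 1, 2 and 3. In control-labelled libraries 1, 2 and 3 it was -0.06, 0.10 and -0.02. Without control-labelled library 2, 11 of the 26 were called higher. Irf7 and Ly6c2 passed in 6 of 6 runs that left out 1 library, Gnl3 in 4 (adjusted p up to 0.0663 without control-labelled library 3 or knockout-labelled library 3), Rtp4 in 3, Oas1a in 2, and Ifih1, Isg20, Mrto4, Nolc1 and Nop2 in 1, that without control-labelled library 2 (up to 0.0846, 0.109, 0.107, 0.104, 0.127, 0.172 and 0.171 in the others).

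Cell cycle genes split the control-labelled libraries. Mki67, the proliferation marker Ki-67, measured 5680, 11469 and 5143 normalized counts in control-labelled libraries 1, 2 and 3 and 7409, 7846 and 10210 in the knockout-labelled ones (log2 fold change 0.27, 95% interval -0.29 to 0.84, adjusted p = 0.582). All 28 measured genes of G2 and mitosis had a positive log2 fold change, and none passed, over all genes or when adjusted over the list alone. Ccnb1 (log2 fold change 0.68, SE 0.26), Ube2c (0.67, SE 0.26), Cenpe (0.56, SE 0.27) and Birc5 (0.57, SE 0.28) had the smallest p. The list was called higher (camera, adjusted p = 4.76e-05; adjusted p = 0.726 with an estimated correlation). Its median in control-labelled library 2 was 0.77 above the control mean on the log2 scale, above the 0.48, 0.24 and 0.55 of the knockout-labelled libraries, and it was -0.31 and -0.43 in control-labelled libraries 1 and 3. Without control-labelled library 2, 28 of the 28 were called higher. Of 28 S phase genes none passed, over all genes or when adjusted over the list alone, and 26 had a positive log2 fold change. Tyms (0.49, SE 0.17), Fen1 (0.43, SE 0.17) and Tk1 (0.51, SE 0.21) were among those with the smallest p, as was Cdt1 with a negative value (-0.22, SE 0.07). That list was called higher (camera, adjusted p = 0.000957; adjusted p = 0.738 with an estimated correlation). Its median was 0.53 in control-labelled library 2 and 0.40, 0.14 and 0.45 in the knockout-labelled libraries. Without control-labelled library 2, 22 of the 28 were called higher, and the list's call was lost without control-labelled library 1 (adjusted p = 0.0555) or 3 (0.0748).

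Of the lists of mitochondrial, ribosomal and lipid genes, 1 member rose and none fell, and on all 3 the median of control-labelled library 2 lay among those of the knockout-labelled libraries. On the log2 scale against the control mean it was 0.13 for oxidative phosphorylation (0.26, 0.13 and 0.09 in knockout-labelled libraries 1, 2 and 3), 0.10 for ribosomal proteins (0.19, 0.10 and -0.02) and 0.11 for fatty acid genes (0.07, 0.13 and 0.14). Without control-labelled library 2, 9 oxidative phosphorylation genes, 4 ribosomal protein genes and 5 fatty acid genes were called higher and none lower. In the main fit oxidative phosphorylation genes had a median log2 fold change of 0.15, and 25 of 26 were positive. None passed, over all genes or when adjusted over the list alone, with Uqcrq (0.23, SE 0.07), Ndufb3 (0.27, SE 0.09), Cox7c (0.24, SE 0.08) and Atp5b (0.26, SE 0.10) at the smallest p. Camera called this list higher (adjusted p = 0.000183; adjusted p = 0.69 with an estimated correlation). Of 34 cytosolic ribosomal protein genes none passed by either adjustment, Rps25 (0.27, SE 0.08), Rpl15 (0.22, SE 0.08), Rpl23 (0.19, SE 0.08) and Rpl7 (0.20, SE 0.09) having the smallest p. The list, with a median of 0.08, was called higher (camera, adjusted p = 0.0111; adjusted p = 0.749 with an estimated correlation), a call lost without control-labelled library 1 (adjusted p = 0.29) or knockout-labelled library 1 (0.154) or 2 (0.0555). Of 17 genes of fatty acid synthesis and oxidation 1 rose (2 when adjusted over the list alone) and none fell. It was Scd2, a stearoyl-CoA desaturase (1.52-fold, adjusted p = 0.0275), which passed in 1 of 6, that without control-labelled library 2, among the runs that left out 1 library (up to 0.112 in the others). Acaca (0.30, SE 0.08), Acadvl (0.25, SE 0.08) and Elovl6 (0.39, SE 0.15) did not pass. Camera called the fatty acid list higher (adjusted p = 0.0143; adjusted p = 0.591 with an estimated correlation), a call lost without control-labelled library 1 (adjusted p = 0.13) or knockout-labelled library 2 (0.0555), and without knockout-labelled libraries 2 and 3 together (0.203).

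Transcripts of B cells were raised in 2 of the 3 knockout-labelled libraries. The median of the 13 measured B cell markers stood at the control mean (0 on the log2 scale) in knockout-labelled library 1, and 2.24 and 2.30 above it in libraries 2 and 3. All 13 had a positive log2 fold change. Of them 2 rose, Cd22, an inhibitory receptor of B cells (2.97-fold, adjusted p = 0.000465), and Ighm, the IgM heavy chain (1.62-fold, adjusted p = 0.0027), and 12 rose when adjusted over the list alone. These 2 were also higher in knockout-labelled library 1. Cd22 measured 734, 1090 and 1045 normalized counts in knockout-labelled libraries 1, 2 and 3 against 302 to 328 in the controls, and Ighm 4784, 5325 and 4931 against 2883 to 3518. Ebf1 (log2 fold change 1.17, SE 0.32) and Ighd (1.06, SE 0.36) did not pass. The list was called higher (camera, adjusted p = 1.52e-07; adjusted p = 0.548 with an estimated correlation), but not without knockout-labelled libraries 2 and 3 (adjusted p = 0.563). Plasma cell markers behaved alike. Of 7 measured 2 rose (3 when adjusted over the list alone), Igkc, the kappa light chain (399, 1204 and 966 normalized counts in the knockout-labelled libraries, 226 to 315 in the controls, adjusted p = 0.0276), and Jchain (3.06-fold, adjusted p = 0.0314), while Ighg1 (log2 fold change 1.89, SE 0.64) and Ighg2c (2.63, SE 1.03) did not pass. Igkc and Jchain lost their calls without control-labelled library 3 or knockout-labelled library 2 or 3 (adjusted p up to 0.138 and 0.152). Plasma cell markers were called higher as a list (camera, adjusted p = 0.00235; adjusted p = 0.571 with an estimated correlation; adjusted p = 0.716 without knockout-labelled libraries 2 and 3).

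Of 9 dendritic cell markers, many of them shared with B cells, 1 rose (6 when adjusted over the list alone), the factor gene Irf8 (1.45-fold, adjusted p = 0.0435), which lost its call without control-labelled library 1 or 3 or knockout-labelled library 2 or 3 (up to 0.177). Cd74, the MHC class II invariant chain, measured 853, 2266 and 2196 normalized counts in the knockout-labelled libraries and 579 to 894 in the controls (adjusted p = 0.0566), and H2-Aa (log2 fold change 0.94, SE 0.26) and H2-Eb1 (1.03, SE 0.29) did not pass. Camera called the dendritic cell list higher (adjusted p = 0.00292; adjusted p = 0.548 with an estimated correlation; adjusted p = 0.208 without knockout-labelled libraries 2 and 3). Neutrophil markers were called higher as a list (camera, adjusted p = 0.0106; adjusted p = 0.591 with an estimated correlation), with none of 7 members passing over all genes and 1 rising when adjusted over the list alone. S100a9 (0.95, SE 0.28), S100a8 (0.84, SE 0.32), Ngp (1.44, SE 0.49) and Retnlg (1.80, SE 0.78) had the smallest p, S100a9, the most abundant, measuring 75.3 ± 33.3 and 138 ± 19.1 normalized counts (SD, n = 3 each). That call was lost without control-labelled library 1 (adjusted p = 0.0747) or 2 (0.0603) or knockout-labelled library 2 (0.0555), and without knockout-labelled libraries 2 and 3 together (0.487). The CD4 and regulatory T cell list was called lower (camera, adjusted p = 0.00303, but 0.259 with an estimated correlation), also by fry (adjusted p = 0.0142). Its median was -0.49, -0.30 and -0.52 in knockout-labelled libraries 1, 2 and 3. Of its 8 measured members 3 fell, Cd40lg, Il2ra and Gata3 (4 fell and 1 rose when adjusted over the list alone), genes that activated CD8+ T cells also express, while Zbtb7b (log2 fold change 0.31, SE 0.10) did not pass. Gata3, a transcription factor, was 1.38-fold lower (adjusted p = 0.0145) and lost its call without control-labelled library 3 or knockout-labelled library 2 or 3 (up to 0.0839).

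**Figure D3:**
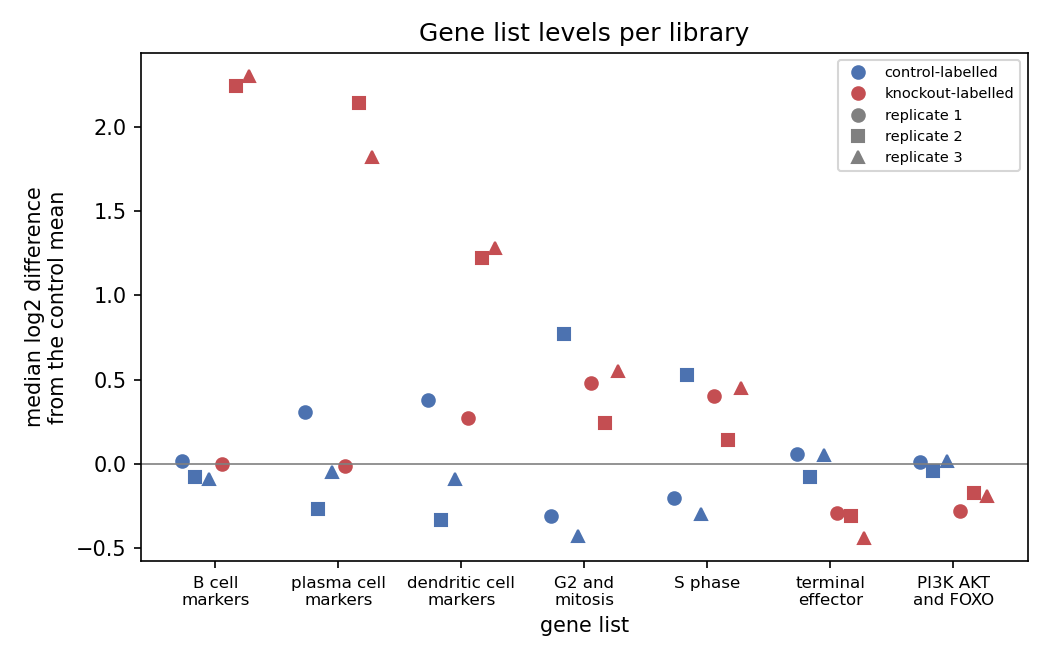
Median log2 difference from the control mean (vertical axis) of the genes on 7 lists (horizontal axis) in each of the 6 libraries, each point being 1 library. B cell markers stand at 2.24 and 2.30 in knockout-labelled libraries 2 and 3 and at 0 in library 1, G2 and mitosis genes stand highest in control-labelled library 2 (0.77), and the terminal effector and PI3K lists lie below the controls in all 3 knockout-labelled libraries.

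None of the remaining 17 lists was called. Among 21 genes of glycolysis and the hypoxia response Slc16a3, a lactate exporter, fell from 189 ± 18.5 to 126 ± 12.3 normalized counts (SD, n = 3; list adjusted p = 0.772), and among 22 genes of cholesterol synthesis Mvd fell 1.48-fold (list adjusted p = 0.645, with a median of 0.01 and a mean of -0.02). Sesn1 was the 1 fall among 23 p53 target genes (0.914), and Itgb3, an integrin beta chain also made by T cells, was 1.49-fold lower among 4 platelet markers (0.181; 2 fell when adjusted over the list alone). Single rises were those of Traf1, an adaptor of TNF receptors, among 22 NF-kappaB genes (1.33-fold; list adjusted p = 0.513, with a median of -0.01 and a mean of 0.04), Tcf7 among 18 WNT genes (0.443), Gzma among 9 NK cell markers (0.233), Irf8 among 26 genes of interferon gamma response and antigen presentation (0.386; none when adjusted over the list alone), and Cd68 among 15 monocyte and macrophage markers (1.51-fold; list adjusted p = 0.694, with a median of -0.07 and a mean of 0.01). No member passed among 16 inhibitory receptor genes (0.446; 2 rose and 4 fell when adjusted over the list alone), 27 genes of the unfolded protein response (0.203; none by either adjustment) or 6 erythroid markers (0.772; none by either adjustment). Where no other number is given, the count adjusted over the list alone was the same. Of these lists, 4 were called under an alternative. The interferon gamma list was called higher after quantile normalization (adjusted p = 0.0395), NK cell markers higher without control-labelled library 3 (0.00296) and platelet markers lower without knockout-labelled library 3 (0.0436). The unfolded protein response list was called higher after quantile normalization (0.00653), without knockout-labelled library 2 (0.017) or 2 and 3 (0.000999) and with a B cell covariate (0.00135). Among the runs that left out 1 library Traf1 passed in 6 of 6, Mvd in 4 (adjusted p up to 0.0697 without control-labelled library 3 or knockout-labelled library 3), Itgb3 in 2 (up to 0.133, lost without control-labelled library 3 or any knockout-labelled library), and Cd68 and Slc16a3 in 1, that without control-labelled library 2 (up to 0.158 and 0.194 in the others).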

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

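The alternatives without knockout-labelled libraries 2 and 3 and with a B cell covariate were chosen after the data were seen. Camera with an estimated correlation and fry were set beside the list test when the lists were fixed, and the others were planned. The number of called genes, 708, moved between alternatives. It was 141 without a variance trend (80 higher, 61 lower), 2676 with array weights (1315 and 1361, with a weight of 0.398 for control-labelled library 2 and 2.53 for 3). It was 140 with a minimum of 2-fold (101 and 39), 135 with the B cell covariate of 11 markers (49 and 86), and 86 with all 13 (34 and 52). Leaving out 1 library gave 200 to 2028 genes (82 to 1046 higher, 118 to 982 lower), the lowest without knockout-labelled library 3 and the highest without control-labelled library 2. Without knockout-labelled libraries 2 and 3 together limma called 0 genes (0 higher, 0 lower; 1861 at an unadjusted p below 0.05) and edgeR 0 (1862), with 1 knockout-labelled library left, assumed to vary like the controls. With the replicate block 197 genes were called (89 higher, 108 lower). Samples that share a number share only that, as their deviations from the group means correlated at -0.54, -0.27 and -0.23, and none correlated best with its own number. The cause of these shifts was not tested, except that the 2-fold minimum only removes genes. The pseudocount, the filter, TMM factors, quantile normalization, edgeR and DESeq2 gave 613 to 1023 genes.

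Csnk2a1 is 1.65-fold higher and so falls outside a minimum of 2-fold. In the other alternatives fitted gene by gene it was higher and was called in all but that without knockout-labelled libraries 2 and 3, with log2 fold changes of 0.69 to 0.77 as single libraries were left out. There it was 0.72 and did not pass (adjusted p = 0.126, against 1.57e-14 to 0.0268 in the others). Of the 92 called genes named in the text, 42 passed with each library left out and 50 lost the call in at least 1 run. Of the 92, 65 lost it without a variance trend, 45 with the replicate block and up to 8 with another scaling, pseudocount, filter or count test. With the B cell covariate 60 lost the call (71 with all 13 markers), and 0 were called without knockout-labelled libraries 2 and 3.

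The number of lists called was 12 to 17 as single libraries were left out, 0 with an estimated correlation and 7 with fry. Of the lists of other cell types, 5 were called, 4 to 6 as single libraries were left out, 0 with an estimated correlation, 1 with fry, 1 without knockout-labelled libraries 2 and 3 and 1 with either B cell covariate. Lists not called were left out of the comparison of directions after their signs had been seen to turn, and 6 of these 20 lists were called under at least 1 alternative. They were the CK2 subunit, trafficking, interferon gamma, unfolded protein response, NK cell and platelet lists. With all 13 markers in the covariate 6 of the 17 called lists lost the call. A list p without knockout-labelled libraries 2 and 3 rests on 1 knockout-labelled library and on the spread over genes, not on replicates of that group.

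Signs turned for genes that were not called. Csnk2a2 was 0.0077 with TMM factors, 0.0255 after quantile normalization and 0.008 with edgeR, and from -0.0247 to 0.0152 as single libraries were left out. Csnk2b ranged from -0.048 to 0.0893 and Ifng from -0.3556 to 0.045 in those runs. Ifng was 0.0656 without knockout-labelled libraries 2 and 3 and 0.0334 with the B cell covariate (0.06 with all 13 markers). Without knockout-labelled libraries 2 and 3, Cd79a was -0.3069 and Ighg1 -0.0076, and Cd79a was -0.202 with the covariate (-0.3869 with all 13). The cause was not tested. At this depth genes with means near 10 normalized counts, such as Ighg2c in the controls, carry wide errors.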

Other observations

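The tests of the 3 patterns weighed here, Csnk2a1, the B cell transcripts and control-labelled library 2, were chosen after the results were seen, and those of Csnk2a1 against B cell RNA, of Cd22 and of the B cell marker list were revised after their first values; the splits of the libraries were planned.

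Genes of cell death moved in both directions. Bcl2l11, which encodes BIM, a killer of T cells at the end of a response, fell from 1571 ± 137 to 797 ± 42.5 normalized counts (SD, n = 3; 1.97-fold lower, log2 fold change -0.98, SE 0.08, adjusted p = 0.000427). Bmf, another pro-apoptotic member of the family, rose from 133 ± 11.9 to 251 ± 46.5 (1.87-fold, adjusted p = 0.00998). Both passed in 6 of 6 runs that left out 1 library. Bbc3 did not pass (log2 fold change -0.36, SE 0.11, adjusted p = 0.102). Of 25 measured genes 1 rose and 1 fell (1 and 2 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.386). Cd163l1, a scavenger receptor found on gamma delta T cells, rose from 118 ± 22.4 to 323 ± 14.8 (2.75-fold, adjusted p = 0.00106) and passed in 6 of 6 runs, while Trdc, the delta chain constant gene, did not pass (log2 fold change -0.21, SE 0.08). These were 2 of 4 measured gamma delta markers, of which 1 rose by either adjustment (1 when adjusted over the list alone; list adjusted p = 0.336).

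On the list of amino acid and stress response genes, Asns and Aars, the alanyl-tRNA synthetase, rose (2 of 20, and 2 rose and 1 fell when adjusted over the list alone; adjusted p = 0.296). Aars was 1.25-fold higher and passed in 2 of 6 runs that left out 1 library (adjusted p up to 0.123). Cd69, an early activation receptor that retains T cells in tissue, rose 1.41-fold (adjusted p = 0.0378) and passed in 3 of 6 runs (up to 0.154). With Itgae it was 1 of 2 rises, beside the fall of Itga1, among 11 tissue residency genes (2 and 1 when adjusted over the list alone; adjusted p = 0.748). It was also the 1 rise among 24 immediate early genes, where Il2ra and Icos fell (6 rose and 2 fell when adjusted over the list alone; adjusted p = 0.862). Icos, a costimulatory receptor, was 1.28-fold lower and passed in 1 of 6 runs (up to 0.173).

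Csnk2a1 was higher in the libraries labelled as lacking CK2α. If reads misassigned from the paralogue in the knockout-labelled libraries alone made the whole gain, Csnk2a2 would change by -1.68 on the log2 scale. Its change was -0.0045 (95% interval -0.15 to 0.14), which argues against that case. A partial share, or misassignment in both groups, was not tested. With the B cell transcript level as a covariate the change of Csnk2a1 was 0.7263 (limma, adjusted p = 0.0173, and 0.73 and 0.0264 with all 13 markers). In knockout-labelled library 1 Csnk2a1 measured 2828 normalized counts, against 1645 to 1847 in the controls. The median of the B cell markers there stood at the control mean. The covariate restates this and is no independent test. B cell RNA as the whole cause is thus argued against by that library alone. Exchanged group labels stay open: a 1.65-fold rise is what they could give, and a raised read count of a partly deleted gene could give it too, so the 2 cannot be told apart without reads over the floxed exons, which were not analysed here. A biological effect of the genotype is likewise untested.

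B cell transcripts stood apart in knockout-labelled libraries 2 and 3, in which 11 of 13 markers were at least 2-fold above the highest control; the count restates the pattern, so B cells or their RNA in those sorts, which a sort on CD8 should remove, stay open as a hypothesis. The most abundant of the 13 listed markers, Ighm, measured 4784 to 5325 normalized counts in the knockout-labelled libraries and 2883 to 3518 in the controls, and all 13 had a control mean of at least 10. For the list as a whole the rise was not shared by all 3 knockout-labelled libraries, though for Cd22 and Ighm it was. The median over all 13 was 0 in knockout-labelled library 1, against 2.24 and 2.30 in the others. These medians are the pattern itself and no separate test of its cause. With 11 markers as a covariate, Cd22 and Ighm set apart after their values were seen, the change of Cd22 was 1.2356 (limma, adjusted p = 0.0103). With all 13 it was 1.20 (0.0166). Cd22 had already been seen raised in knockout-labelled library 1, where the median of the markers was not. The covariate restates this and is no independent test of B cell RNA as the whole cause. That cause stays open for Cd22 and for Ighm (0.65, adjusted p = 0.0527, and 0.64 and 0.0691 with all 13). An effect of the genotype on Cd22 is a hypothesis that was not tested further.

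Control-labelled library 2 differed from the other controls in cell cycle genes and in chi-square per degree of freedom (19.1 and 18.5 against them, and 5.32 between them). Against knockout-labelled libraries 1, 2 and 3 its chi-square was lower, at 15.8, 12.9 and 14.6. Control-labelled libraries 1 and 3 also had lower values against knockout-labelled library 2 (16.9 and 18.2) than against control-labelled library 2. Against knockout-labelled libraries 1 and 3 theirs were higher (30.8 and 23.5 for control-labelled library 1, 32.5 and 27.6 for 3). These values were not adjusted for depth. A knockout-labelled sample under a control label is argued against by the gene used for the test, Csnk2a1. In control-labelled library 2 it lay 0.21 of the way from the other controls (0) to the knockout-labelled mean (1). Of other named genes, Cd6 (0.03), Cd40lg (0.07) and Gzmb (-0.37) lay on the control side. Zeb2 (0.81) and Mki67 (1.705) lay on the knockout-labelled side. Over the 2028 genes called without that library the median position was 0.54, with 46.4% nearer the controls. It thus lay between the groups for many genes. With these positions and the chi-square values, this explanation for control-labelled library 2 is not settled. Depth is argued against because its recovered reads lay within the range of the other controls (position 0.27). In it 28 of 28 genes of G2 and mitosis were higher than in both other controls, but the pattern was seen in these same genes, so the count restates it and a larger share of cycling cells stays open as an untested hypothesis.

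The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 708 genes (1 of 10 splits as large) and the highest other 52, from the split that grouped control-labelled library 1 with knockout-labelled libraries 2 and 3. For lists it gave 17 (3 of 10 splits as large) and the highest other 19, from the split that grouped knockout-labelled library 1 with control-labelled libraries 1 and 3. The splits other than the real one called 8, 10, 9, 19, 10, 18, 8, 1 and 12 lists. The number of lists called at the preset correlation thus does not set the labels apart from other groupings.

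The first principal component of the log2 values (40.5% of the variance) did not separate the groups by label. Control-labelled libraries 1, 2 and 3 scored -20.5, 32.1 and 26 on it, and knockout-labelled libraries 1, 2 and 3 scored 16.3, -27.9 and -25.9, so that control-labelled library 1 lay with knockout-labelled libraries 2 and 3. On the second (28.5%) the controls scored -36.2, 2.7 and -19.3 and the knockout-labelled libraries 25.3, 14.3 and 13.1. Genes at 0 grouped as on the first component. They numbered 3, 0 and 1 in control-labelled library 1 and knockout-labelled libraries 2 and 3. In control-labelled libraries 2 and 3 and knockout-labelled library 1 they numbered 19, 17 and 17. Deviations from the group means correlated at 0.34 and 0.37 across the former, and at 0.39 and 0.28 across the latter. This grouping is also the split that called 52 genes, and its cause was not tested.

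Hspa1b, a stress-induced chaperone, measured 7948 normalized counts in knockout-labelled library 3, 2406 and 1317 in knockout-labelled libraries 1 and 2, and 477 to 1256 in the controls (adjusted p = 0.0693). Xist measured 136 in control-labelled library 1 and 0 to 1.68 in the other libraries.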
